A study of Macaca mulatta with 6 samples.

How the data were processed

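RNA of 6 single colonies was reverse transcribed with the SMART-Seq V4 kit and turned into Nextera XT sequencing libraries, per the labels' protocols. This kit amplifies full-length cDNA from few cells and marks neither strand nor molecule, so antisense and overlapping genes cannot be told apart and PCR copies are counted as reads. The submitters' processing notes name the genome build Mmul_8.0.1 and the demultiplexing tool bcl2fastq. The aligner and the counting tool are not given in the sources used here. The authors deposited a table of raw counts per gene for the 6 libraries, with no normalization, and these counts are whole numbers with totals that differ between libraries. They also deposited a table of differential expression, whose columns are, per the file headers, a mean of normalized counts (used as a signal), a log2 fold change with its standard error, a test statistic (a score), a p-value and an adjusted p-value. Its names for the mean, fold change, standard error and statistic are those DESeq2 writes, while those for the p-values (p.value and p.adj) are not. Which libraries the authors compared in it is not given in the sources used here.

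The count table has 32386 rows, 29857 named by Ensembl ID and 2529 by gene symbol. Symbols came from the authors' deposited table for 9226 IDs and from a table of gene names for 7223 more, and 13408 IDs have none. The 2 sources gave different symbols for 396 of 7915 IDs paired by both, and the deposited one was used. For the 189 symbols on more than 1 row, the row with the highest total count was used in gene lists. No reference genome was used here, so gene coordinates are those of the authors' deposited table and GC content and gene length were not examined. All 6 libraries were mapped to their labels by title, and no column of another sample was present.

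Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust=TRUE, on all 6 libraries with the label as the only term. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 13768 genes, and libraries were scaled by TMM, with factors of 0.86 to 1.07. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 0.232. Means and SDs are of TMM-scaled CPM over 3 libraries. For a gene with 0 counts in a whole group, the fold is a bound against 3 counts over that group, and with 1 to 3 counts a ratio with a 95% exact counting interval, both on TMM-scaled totals and covering counting error only. A count of 0 allows up to 0.137 CPM in the deepest library and 0.443 CPM in the shallowest.

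Named genes followed a rule set before the data were examined. They are TET2, the 12 genes with the largest log2 fold change in each direction among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, and members of fixed gene lists that passed. Another rule let up to 4 members of smallest p be named per list. The 32 lists were fixed before the data were examined. They cover genes linked to DNA methylation, inflammation and interferon, MHC class II, cell cycle, ribosomal and mitochondrial genes, metabolism and stress responses. Others cover myeloid, stem, erythroid, megakaryocyte, mast cell and eosinophil, dendritic, lymphoid and stromal markers. The rest cover p53 targets, phagocyte oxidase, lysosome, myeloid transcription factors and histones. Lists with at least 5 tested members were tested with limma 3.58.1's camera on log2 CPM (prior count 2) at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 32 lists. Setting the members with 0 counts in a group, 1 in each of 2 lists, to their bound left every list median as it was.

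The fit was tested on simulated counts for the comparison of UA against WT, drawn for the 13768 genes from the real means and library sizes. It recovered 41% of 100 genes changed by 1 on the log2 scale and 90% of 100 changed by 2, with 10 false among 141 calls (7.1%). The changed genes rose and fell in equal number and had more than 10 expected counts in the smallest library. They were a small part of the genes in the fit, whereas 66% were called in the real comparison. These shares therefore need not hold there. Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, library size alone, no low-count filter, a stricter filter (at least 5 CPM in 3 libraries), the DESeq2 test, limma-voom with quality weights, a replicate block, 1 surrogate variable (sva 3.50.0), robust=FALSE, an adjusted p under 0.1, removal of mitochondrial and ribosomal protein genes, and leaving out each library. For lists, an estimated correlation and limma's fry were tried too. After the data were seen, a sum of the 3 UA libraries and thinning of all libraries to the smallest total were added. Spread between a pair of libraries was measured as the median chi-square of a gene's split of counts over its median under counting noise.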

Results

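RNA was sequenced from 6 colonies of rhesus macaque bone marrow cells, 3 labelled TET2 wild type (WT) and 3 labelled TET2 uniallelic (UA). The colonies were granulocyte-macrophage colonies (CFU-GM), each grown in semi-solid medium for 14 days from a single CD34+ blood stem or progenitor cell. The cells came from marrow taken 15 months after transplantation of autologous, CRISPR/Cas9-treated CD34+ cells, and each colony's genotype had been read from its DNA. TET2 encodes an enzyme that oxidizes 5-methylcytosine in DNA, and its loss-of-function mutations are common in clonal hematopoiesis. Total counts were 25485143, 10574104 and 12005869 in WT replicates 1 to 3, and 17684447, 9861817 and 6334264 in UA replicates 1 to 3. The labels do not say how many animals the colonies came from. The p-values therefore measure the spread between these libraries, which may be partly technical. For the UA-labelled ones it may be wholly so, since 1 RNA source could not be told apart from 3 similar colonies, as described below.

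The first question was how gene expression differed between TET2-mutated and unmutated colonies. TET2 itself was higher in the UA-labelled libraries, at 231 ± 6.65 CPM, counts scaled by library total and TMM factor (SD, n = 3), against 93.8 ± 14.9 (SD, n = 3) in the WT-labelled ones. Its log2 fold change was 1.30 (SE 0.16, edgeR adjusted p = 3.93e-05), and its counts were 1736, 971 and 1296 in WT and 4387, 2336 and 1554 in UA replicates 1 to 3. Reads of the edited allele were not examined, so these counts do not show whether an allele was lost, and the higher level in the mutant-labelled group does not check the labels. For that reason the libraries are named below by their labels. TET2 lies on chromosome 5 from 105087660 to 105219996 in the authors' deposited table, which names no build, while the submitters' processing notes name Mmul_8.0.1.

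The UA-labelled libraries held far more transcript of most primary granule proteins, and also of most marker genes of megakaryocytes, endothelium and stroma. The WT-labelled libraries held far more CCL1, CCL2 and CD14 and more of most genes of cholesterol synthesis and mitochondrial respiration, while CCL5 rose in UA by 4.35 on the log2 scale. No gene list was called with an estimated correlation between genes. MPO, the peroxidase of azurophil granules, had 16740 ± 147 CPM in UA and 810.4 ± 114 in WT (SD, n = 3 each). CCL2, a monocyte-attracting chemokine, had 11.2 ± 1.90 CPM in UA and 3400 ± 1355 in WT. Of 13768 genes tested, 4770 were higher and 4321 lower in UA at an edgeR adjusted p under 0.05, together 66% of those tested. Among these, 3774 were higher and 2949 lower by a log2 fold change beyond 1, and 1084 were higher and 205 lower beyond 3. The 3 colonies of one label all lay above the 3 of the other for 10077 genes (73.2%, where chance gives 10%). With the 3 UA libraries summed to 1 sample, so that all spread comes from the 3 WT libraries, a fit chosen after the data were seen called 2950 genes higher and 2410 lower.

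**Figure D1:**
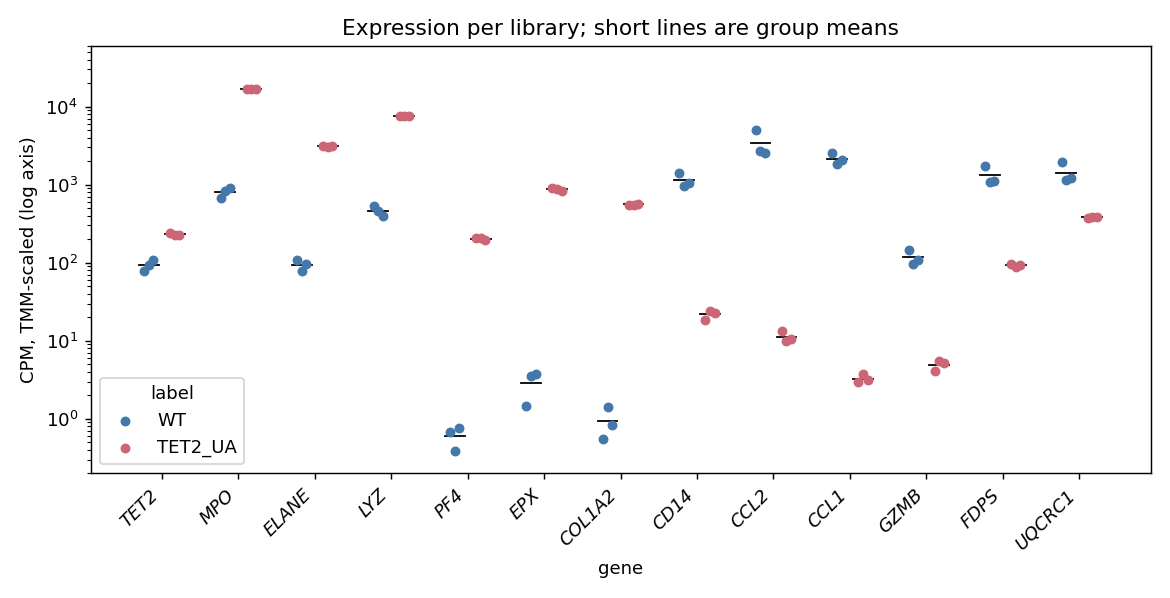
CPM (TMM-scaled, log axis) of 13 genes in each of the 6 libraries, with 1 point per library and short lines at the group means. For every gene drawn the 3 UA-labelled points lie on one side of the 3 WT-labelled points, as for MPO at 16740 against 810.4 CPM on average.

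Among the 12 genes with the largest rise, TM4SF18, SPARCL1, TINAGL1, SNED1, NTSR1, MMRN2 and IQSEC3 had 0 counts in all 3 WT-labelled libraries. Against a floor of 3 counts over the WT group, with TMM-scaled totals, they were at least 274-fold, 214-fold, 214-fold, 211-fold, 192-fold, 187-fold and 168-fold higher in UA, in that order. SELE, an adhesion molecule of activated endothelium, had 1 count in WT and 1543 in UA, a ratio of 1920 with a 95% counting interval of 343 to 75700. TIMD4, a phosphatidylserine receptor of tissue macrophages, had a ratio of 1570 (280 to 61900). ADGRL4, an endothelial adhesion receptor, had one of 1200 (214 to 47300), and SCUBE3, a secreted glycoprotein, one of 835 (231 to 6910). COL1A2, a chain of type I collagen, rose from 0.942 ± 0.451 to 560.0 ± 11.9 CPM (SD, n = 3 each), a log2 fold change of 9.32 (SE 0.29, edgeR adjusted p = 9.29e-09).

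The 12 genes with the largest fall included 3 of cytokines, CCL1, CCL2 and CSF2. CD207, the langerin of Langerhans cells, had 3586 counts in WT and 3 in UA, a ratio of 963 (329 to 4670). CCL1, a chemokine, fell from 2151 ± 350 to 3.28 ± 0.414 CPM, a log2 fold change of -9.36 (SE 0.23, edgeR adjusted p = 2.89e-09). CSF2, which encodes the growth factor GM-CSF, had a log2 fold change of -9.03, ALDH3A1, an aldehyde dehydrogenase, -8.34, and CCL2 -8.23 (SE 0.43, 0.35 and 0.34). TNFRSF18, a receptor of activated T cells, had a log2 fold change of -8.01, NTS, the precursor of neurotensin, -7.80, and IL4I1, an amino acid oxidase, -6.61. TMEFF2 and ACKR1, a chemokine-binding receptor, both had a log2 fold change of -6.06, and CD14, the lipopolysaccharide co-receptor of monocytes, one of -5.73 (SE 0.22). CYP3A5, a drug-metabolizing enzyme, had 846 counts in WT and 3 in UA, a ratio of 227 (77.5 to 1100). Each of these 12 was lower in 3 of 3 UA-labelled libraries, with an edgeR adjusted p of at most 1.44e-05.

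In neutrophil primary granule genes 11 of 12 tested members rose and none fell, with a median log2 fold change of 3.53 (camera adjusted p = 6e-05, adjusted p = 0.13 with an estimated correlation). ELANE, neutrophil elastase, rose from 94.2 to 3111 CPM, CTSG, cathepsin G, from 219 to 3870 CPM, and AZU1, azurocidin, from 75.9 to 799.6 CPM. Adjusted over the list alone, 11 rose and 1 fell. Genes of later neutrophil granules and maturation were mixed, with 10 of 19 higher, 4 lower and 5 not passing (camera adjusted p = 0.21). There CSF3R, the G-CSF receptor, rose by a log2 fold change of 4.04 and LTF, lactoferrin, by 6.82, while MMP9 and LCN2 had log2 fold changes of -3.04 and -3.43.

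Monocyte and macrophage markers rose in 16 of 25 tested members, fell in 3 and did not pass in 6, with a median log2 fold change of 1.60 (camera adjusted p = 0.0033, adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 17 rose and 3 fell. LYZ, lysozyme, which granulocytes also make, rose from 464 to 7600 CPM, C1QC, a complement chain, by a log2 fold change of 4.77 and GPNMB by 4.93, while CD14 fell. CD163, a scavenger receptor of tissue macrophages, rose by 1.51 on the log2 scale. Dendritic cell markers went both ways, with 4 of 12 higher and 6 lower (camera adjusted p = 0.41). CD207, CD1B and BATF3 fell, the latter pair with log2 fold changes of -4.99 and -4.50, and IRF8, a transcription factor of monocytes and dendritic cells, rose by 2.13. Of 9 MHC class II genes tested, 3 rose and 2 fell (camera adjusted p = 0.78), among them HLA-DOA with a log2 fold change of 1.83 and HLA-DRB5, whose reads related genes may share, with -0.73 (-0.69 and an edgeR adjusted p of 0.136 in the smaller summed fit).

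Markers of megakaryocytes and of stroma and endothelium rose in the same libraries. Megakaryocyte markers rose in 9 of 15 tested members and fell in 1, with a median log2 fold change of 3.65 (camera adjusted p = 0.0038, adjusted p = 0.13 with an estimated correlation). PF4 and PPBP, platelet chemokines, rose from 0.608 to 203.5 and from 0.614 to 258 CPM, ITGA2B by a log2 fold change of 5.84, and TUBB1 fell by 1.11 on the log2 scale. Adjusted over the list alone, 10 rose and 1 fell. Stromal and endothelial markers rose in 11 of 13 and fell in 2, with a median log2 fold change of 4.83 (camera adjusted p = 0.0015, adjusted p = 0.13 with an estimated correlation). COL1A1 rose by a log2 fold change of 8.60 and CDH5, the cadherin of endothelium, by 5.22, while DCN, decorin, fell from 113 to 21.6 CPM.

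Mast cell, basophil and eosinophil markers rose in 9 of 13 and fell in 2 (camera adjusted p = 0.065). EPX, eosinophil peroxidase, rose from 2.90 to 877 CPM and PRG3, an eosinophil granule protein, from 10.99 to 499 CPM, while IL1RL1 had a log2 fold change of -3.63. Of 11 lymphoid markers, 7 rose and 4 fell (camera adjusted p = 0.41). CD79A, a B-lineage gene, rose by a log2 fold change of 3.03, while GZMB, granzyme B, and IL7R had log2 fold changes of -4.60 and -2.23. Erythroid markers rose in 7 of 13 and fell in 5 (camera adjusted p = 0.84), with TFRC, the transferrin receptor, at a log2 fold change of 2.63 and RHAG at -4.06. Stem and progenitor genes rose in 6 of 19 and fell in 9 (camera adjusted p = 0.41). MYB and FLT3 rose by 2.23 and 2.32 on the log2 scale, and HOXA9 and MLLT3 had log2 fold changes of -2.09 and -2.51. CD34, named after its values were seen, had 311 ± 7.45 CPM in UA and 333 ± 84.0 in WT (SD, n = 3 each), a log2 fold change of -0.10 (SE 0.19, edgeR adjusted p = 0.653) whose sign turned to 0.043 with library size alone. It was called lower without WT replicate 1 (-0.29, edgeR adjusted p = 0.00153) and with limma-voom (-0.25, adjusted p = 0.0251).

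Cytokine and chemokine genes fell more often than they rose, in libraries that also differed in the lineage markers above. Pro-inflammatory cytokines and chemokines fell in 11 of 20 and rose in 3, with a median log2 fold change of -1.37 (camera adjusted p = 0.0037, adjusted p = 0.13 with an estimated correlation). WT replicate 1 was 1.27 times the other WT libraries at the median, and without it the list's median was -0.89 (camera adjusted p = 0.00746). Besides CCL2, EBI3, CXCL1, CCL7 and IL1A had log2 fold changes of -4.66, -3.63, -5.63 and -3.26, while CCL5 rose by 4.35. IL6 had 2.50 ± 0.667 CPM in UA and 8.14 ± 5.10 in WT (log2 fold change -1.71, edgeR adjusted p = 0.0095), and without WT replicate 1 it had a log2 fold change of -1.08 and was not called (edgeR adjusted p = 0.0588). In the summed fit, where all spread comes from the WT libraries, its log2 fold change stayed at -1.71. TNF was higher in UA by 0.75 on the log2 scale (edgeR adjusted p = 0.0114), and by 0.69 without UA replicate 2 (edgeR adjusted p = 0.0544) and 0.76 in the summed fit (0.175). NF-kB signalling genes fell in 12 of 22 and rose in 7 (camera adjusted p = 0.13). TRAF1, NFKB2 and CD40 had log2 fold changes of -3.82, -2.99 and -4.14, and REL and NFKBIZ of 1.80 and 2.22.

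Inflammasome genes rose in 9 of 15 and fell in 4 (camera adjusted p = 0.52). TXNIP and MEFV rose by log2 fold changes of 3.21 and 3.52, while CASP1 and CASP4, inflammatory caspases, fell from 449.9 to 112.5 CPM and from 123 to 33.1 CPM. NLRP3, the inflammasome sensor, was higher by 0.63 (edgeR adjusted p = 0.0216), and by 0.64, 0.62 and 0.63 with UA replicate 1, 2 or 3 left out (edgeR adjusted p = 0.0564, 0.07 and 0.0623) and 0.64 in the summed fit (0.192). Toll-like receptor pathway genes rose in 7 of 18 and fell in 5 (camera adjusted p = 0.84). TLR3 and TLR4 had log2 fold changes of 4.12 and 1.71, and CD14 was lower. TLR3 was very low in WT, at 0.279 CPM against 5.13 in UA. Anti-inflammatory regulators rose in 6 of 14 and fell in 5 (camera adjusted p = 0.81), with HMOX1, heme oxygenase, and ZFP36 at log2 fold changes of 5.19 and 3.09 and IL1RN, the interleukin-1 receptor antagonist, at -2.94. Interferon-stimulated genes rose in 11 of 29 and fell in 3 (camera adjusted p = 0.1), with STAT2 and OAS2 at log2 fold changes of 2.59 and 2.11 and USP18 at -2.48. Phagocyte oxidase genes rose in 3 of 6 and fell in 1 (camera adjusted p = 0.57), with CYBB at a log2 fold change of 2.24 and NCF4 at -2.95.

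Most genes of respiration and cholesterol synthesis fell in the libraries with the higher megakaryocyte, stromal and granule markers. Nuclear oxidative phosphorylation genes fell in 34 of 37 and rose in none, with a median log2 fold change of -1.38 (camera adjusted p = 9.4e-09, adjusted p = 0.46 with an estimated correlation). ATP5MC1, of ATP synthase, and UQCRC1, of respiratory complex III, had log2 fold changes of -2.66 and -1.90. Mitochondrially encoded genes fell in 7 of 8, with MT-ND4 at a log2 fold change of -1.62 (camera adjusted p = 0.014, adjusted p = 0.56 with an estimated correlation). WT replicate 1 held more of both than the other WT libraries, 1.78 times for mitochondrially encoded and 1.57 times for nuclear genes at the median, with MT-ND4 at 893 against 432 and 494 CPM. Without it their medians were -0.80 and -1.17 (camera adjusted p = 0.0043 and 1.64e-10). Cholesterol synthesis genes fell in 19 of 22 and rose in none, with a median log2 fold change of -2.25 (camera adjusted p = 1.8e-07, adjusted p = 0.1 with an estimated correlation). FDPS, SQLE and DHCR7, enzymes of the pathway, had log2 fold changes of -3.84, -2.82 and -3.73, and adjusted over the list alone 20 fell. Glycolysis and hypoxia genes fell in 14 of 21 and rose in 3 (camera adjusted p = 0.01, adjusted p = 0.13 with an estimated correlation). EGLN3 and LDHA, lactate dehydrogenase A, had log2 fold changes of -4.25 and -1.41, and NDRG1 one of 3.18.

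S phase genes fell in 20 of 29 and rose in 2, with a median log2 fold change of -0.54 (camera adjusted p = 0.001, adjusted p = 0.16 with an estimated correlation). FEN1, a DNA replication nuclease, and CCNE1, cyclin E1, had log2 fold changes of -3.28 and -2.03. G2 and M phase genes fell in 13 of 30 and rose in 3 (camera adjusted p = 0.046, adjusted p = 0.37 with an estimated correlation), with CCNB1, cyclin B1, at a log2 fold change of -2.30 and ANLN at 1.33. That call was also lost with library size alone (camera adjusted p = 0.0841), with the stricter filter (0.152), without WT replicate 2 (0.0803), without UA replicate 3 (0.0523) and with the UA libraries summed (0.0626). Cytosolic ribosomal protein genes fell in 44 of 60 and rose in none, with a median log2 fold change of -0.73 (camera adjusted p = 3.3e-06, adjusted p = 0.56 with an estimated correlation), and adjusted over the list alone 45 fell. WT replicate 1 was 1.47 times the other WT libraries at the median here, and without it the median was -0.50 (camera adjusted p = 5.7e-06). RPL8 and RPL27 had log2 fold changes of -1.44 and -1.93, values that are uncertain because processed copies of such genes can share reads. Of 9 histone genes, 1 rose and 3 fell, with H2AZ1, a replication-independent variant, at a log2 fold change of -1.86 (camera adjusted p = 0.52).

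Immediate-early and heat shock genes, which respond quickly to handling as well as to growth signals, rose in 14 of 18 and fell in 3 in the same libraries. Their median log2 fold change was 2.46 (camera adjusted p = 0.0033, adjusted p = 0.13 with an estimated correlation). KLF2, KLF4 and EGR1 rose by log2 fold changes of 4.12, 3.83 and 3.21, while HSPA8, a constitutive chaperone, had one of -1.81. The other heat shock genes tested, HSPH1 and DNAJB1, had log2 fold changes of -0.74 and 0.97. Among immediate-early genes FOS had one of 0.43 and EGR2 one of -1.12, so the list did not move as a whole. Genes of the unfolded protein and integrated stress response fell in 9 of 16 and rose in 5 (camera adjusted p = 0.36), with ASNS at a log2 fold change of -1.96 and HSPA5, the chaperone BiP, at 0.95. Of 18 p53 target genes, 8 rose and 5 fell, and 9 rose adjusted over the list alone (camera adjusted p = 0.81), with SESN1 at a log2 fold change of 1.58 and BAX at -1.61. Lysosomal genes rose in 13 of 29 and fell in 7 (camera adjusted p = 0.49), with PSAP at a log2 fold change of 1.40 and CD63 at -1.06. Myeloid transcription factors rose in 7 of 20 and fell in 7 (camera adjusted p = 0.95), with IRF1 at a log2 fold change of 2.86 and MYC and SPI1 at -2.15 and -1.48. Their median and mean were above 0, at 0.07 and 0.155, while camera's direction was down. Of 12 genes linked to DNA methylation and demethylation, 5 rose and 3 fell (camera adjusted p = 0.71). TET1, TET3 and OGT had log2 fold changes of 4.89, 4.38 and 2.13, and IDH1 and IDH2 of -1.21 and -0.95. TET1 and TET3 were very low in WT, at 0.313 and 0.839 CPM against 9.555 and 17.4 in UA.

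**Figure D2:**
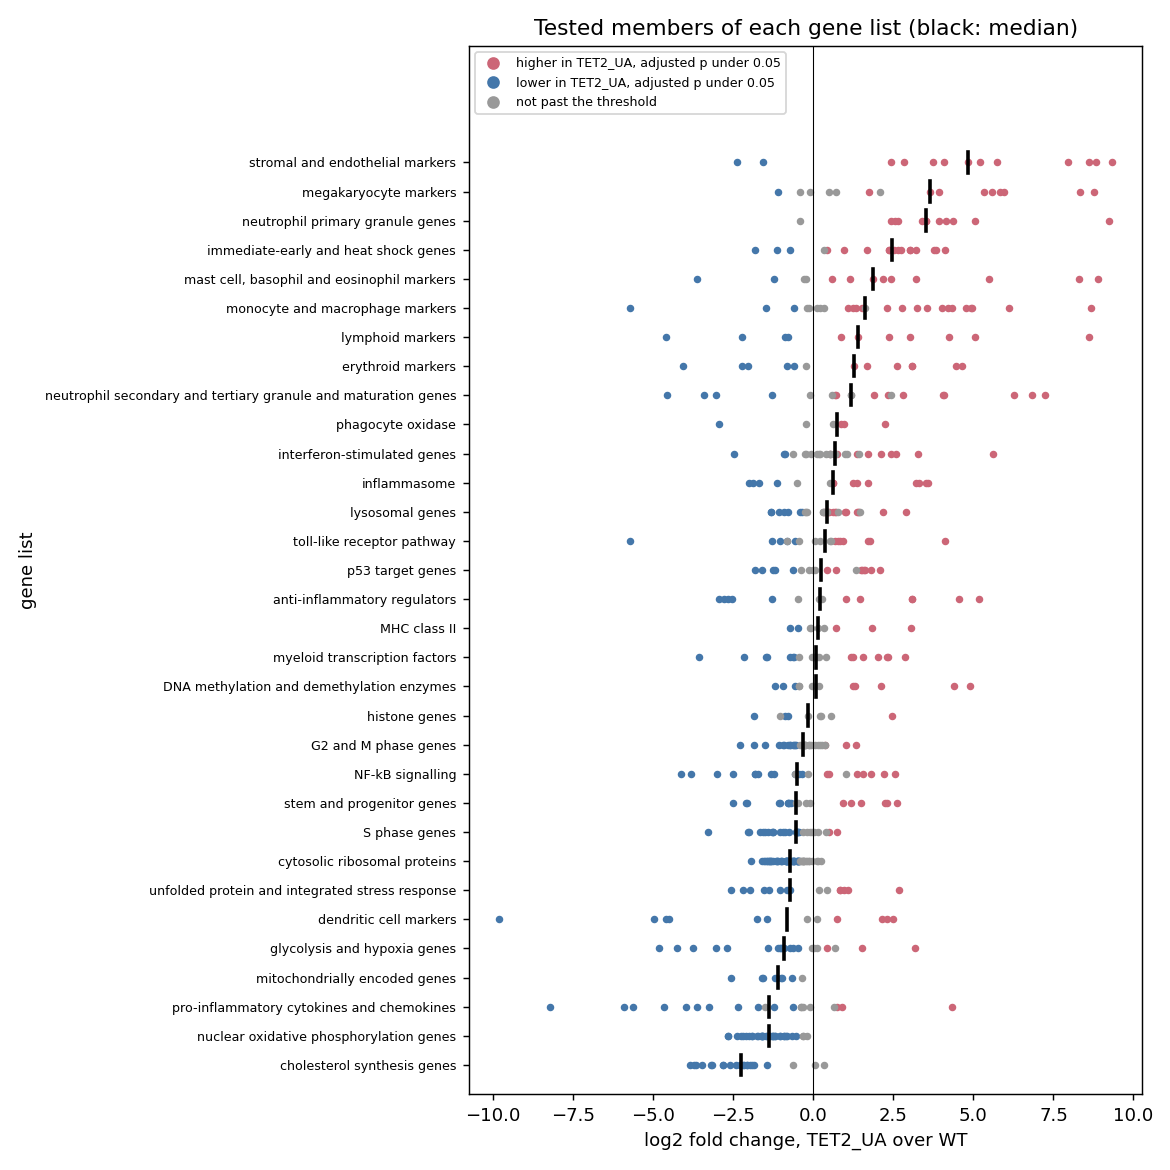
Log2 fold change, UA over WT, of each tested member of the 32 gene lists, coloured by whether and which way it passed an edgeR adjusted p of 0.05, with black ticks at the list medians. Stromal and endothelial markers have the highest median, 4.83, and cholesterol synthesis genes the lowest, -2.25.

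Of the 32 lists, camera with its preset correlation called 5 higher and 8 lower, none was called with an estimated correlation (9 at an unadjusted p under 0.05), and fry called 29. Exact permutation tests of list means per colony, two-sided, cannot go below 0.1 with 3 colonies against 3. They gave 0.1 for every list except stem and progenitor genes (0.3), myeloid transcription factors (0.2), toll-like receptor pathway and histone genes (0.8 each). In all other lists than those named the counts were the same adjusted over the list alone.

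The colonies of one label were not equally alike. Libraries of the UA label correlated at a Pearson r of 0.9745 to 0.982 across genes on the log2 CPM scale, those of the WT label at 0.960 to 0.9675, and those of different labels at 0.7485 to 0.8015, over genes, which are not independent replicates. At an equal depth of 6334264 counts, the median excess of UA pairs over counting noise was 3.10, 3.09 and 3.69, and that of WT pairs 24.5, 23.1 and 7.03. All exceeded 1, the value under counting noise alone, as separately made libraries of 1 RNA would too, and each library was counted as 1 replicate as labelled. At that depth 15443, 14918 and 14821 genes had a count in WT replicates 1 to 3, and 19331, 18992 and 18721 in UA replicates 1 to 3.

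**Figure D3:**
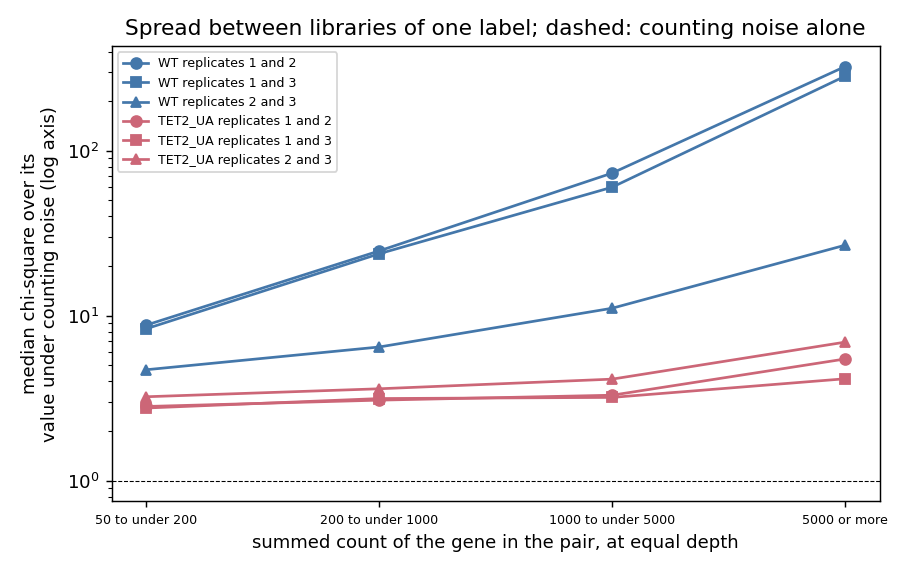
Median chi-square of a gene's split between 2 libraries of one label, divided by its median under counting noise (log axis), by the gene's summed count at equal depth, with 1 line per pair of libraries. UA pairs lie between 2.76 and 6.92, and the WT pairs with replicate 1 rise to 324 and 283.

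A second question was how the counts compare with the fold changes that the authors deposited. MPO, which rose here by 4.37 on the log2 scale, has a log2 fold change of -4.27 in the authors' deposited table, whereas TET2 has 1.73 there, the direction found here. HBA2, an alpha globin, has a mean of 1769228 in the authors' deposited table and 56.4 CPM on average over the 6 libraries. Across 10568 genes tested here and listed in the authors' deposited table, the log2 fold changes correlated at a Pearson r of -0.415 and a Spearman rho of -0.424, over genes, which are not independent replicates. Of 7136 genes called here and listed in the authors' deposited table, 2228 (31.2%) had the same direction in both. If its ratio were written the other way round, the remaining genes would share the direction instead. Its header does not say which samples it compared, and its largest adjusted p is 0.05, so it lists only genes past that threshold.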

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

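Both tests in this part were chosen after the result was seen. Of the 21404 genes of the authors' deposited table found in the count table, 3584 have 0 counts in all 6 libraries, a signal in data that the group comparison does not use. The pattern is the disagreement of fold changes between the authors' deposited table and the counts. A table of the same libraries with its direction turned would correlate at -0.9 or lower across shared genes, and the correlation was -0.415, which argues against it. Another set of libraries behind the table would list genes that these libraries lack, and 489 of those 3584 genes have a listed mean of 10 or more, which that explanation needs. Which libraries these might be, and whether other counting of the same reads could add to the difference, stays open, and no biological explanation was tested.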

How the results depend on the processing

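The sum of the UA libraries and the thinning were chosen after the data were seen. The summed fit called 2950 genes higher and 2410 lower, fewer by its construction of 4 samples, with all spread from the 3 WT libraries. Every other alternative gave between 3989 and 5932 higher and between 3764 and 4675 lower, within 1.5 times of 4770 and 4321, and leaving out a library gave 4133 to 5371 and 3764 to 4578. TET2 had a log2 fold change of 1.20 (without WT replicate 1) to 1.45 (library size alone) and stayed past the threshold throughout. Library size alone moved the median log2 fold change of all genes from 0.12 to 0.28. Lists called numbered 13, or 12 to 14 under scaling, filter, block and leave-one-out alternatives, but 0 by camera with an estimated correlation (9 at an unadjusted p under 0.05) and 29 by fry, which asks whether a list moves one way without comparing it with other genes. Of the 9091 called genes, 8548 were also called at equal depth. Deviations of same-numbered libraries from their group means correlated at 0.013, 0.022 and 0.013, all under 0.1, so the numbers were not taken to pair the colonies. Each library still correlated best with its own number, a hint from the data and not the design. The replicate block gave 4765 higher and 4174 lower, left G2 and M phase genes uncalled (camera adjusted p = 0.0553) and changed no other call of a named gene or list. The share of the authors' table with the same direction, with its ratio taken as listed, was 31.2%, or 32.0% at an adjusted p under 0.1.

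Of 142 genes besides TET2 followed through the alternatives, 137 gave the same direction and side of the threshold under every alternative. Most were named because they passed or changed strongly in this same fit, so their stability partly follows from that choice. CD34 turned to 0.043 with library size alone and ran from -0.29 to 0.007 with a library left out. It passed, lower, with limma-voom (adjusted p = 0.0251) and without WT replicate 1 (edgeR adjusted p = 0.00153). IL6, TNF, NLRP3 and HLA-DRB5 lost their calls as given with their values, TNF, NLRP3 and HLA-DRB5 with little change in fold. Among lists that were not called, medians turned sign for erythroid markers under the stricter filter (-0.37) and histone genes with library size alone (0.033). With a library left out, the median ran from -0.545 to 0.17 for histone genes, from -0.011 to 0.63 for anti-inflammatory regulators and from -0.054 to 0.242 for myeloid transcription factors. NF-kB signalling was called lower with no low-count filter (camera adjusted p = 0.00812). Except where stated, the cause was not tested. Depth limits genes below about 0.443 CPM, the level that 0 counts allow in the shallowest library.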

Other observations

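Gene groups beyond the fixed lists were written down after the values were seen, partly from genes already known to differ, so their counts describe these libraries and are no independent test. Of 17 B-lineage progenitor genes tested, 15 rose and 1 fell in the UA-labelled libraries, with a median log2 fold change of 6.05. DNTT, the terminal transferase of lymphoid progenitors, rose from 5.57 ± 0.951 to 729.5 ± 8.18 CPM (SD, n = 3 each), EBF1 from 1.90 to 288 CPM, LEF1 from 2.11 to 227 CPM and VPREB1, a surrogate light chain, from 2.48 to 274.5 CPM. Of 19 endothelial genes 17 rose and 1 fell, and of 19 collagen and matrix genes 17 rose and 2 fell, with COL6A3 at 586 against 1.09 CPM and VWF at 96.4 against 6.28. Of 15 resident macrophage genes 14 rose and none fell, with SLC40A1, the iron exporter, at 366 against 60.8 CPM and CD5L at 18.6 against 0.300. Of 13 circadian clock genes 8 rose and none fell, with PER1 and NR1D2 at log2 fold changes of 5.15 and 4.89.

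The WT-labelled libraries were higher in other groups written down in the same way. Of 17 genes of activated dendritic cells and T-cell attraction, 16 were lower in UA and none higher, with IDO1 and KYNU, enzymes of tryptophan breakdown, at log2 fold changes of -3.61 and -3.63. Of 18 targets of NRF2, a regulator of oxidative defence, 16 fell and 1 rose, with SRXN1 and AKR1B10 at -3.70 and -5.12. HMOX1, another target of NRF2, was written into the resident macrophage group instead and rose by 5.19 on the log2 scale. All 29 proteasome subunits tested fell, with a median log2 fold change of -1.77 and PSMB5 at -3.21. Spread among the WT libraries was wide for some, as for PSMB5 at 865 ± 280 CPM (SD, n = 3). For others it was small, as for PSMD2 at 1555 ± 17.6 CPM (SD, n = 3). The median of this group without WT replicate 1 was not examined. In these groups 16, 18 and 29 members had at least 5 CPM in the WT-labelled libraries. In the B-lineage, endothelial, matrix, resident macrophage and clock groups only 7, 8, 4, 4 and 5 had, so most of those members lay below that level in WT.

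Tests of a mixed population and of 1 RNA source were chosen after the result was seen, and those of depth before. Most markers pooled from the megakaryocyte, mast cell and eosinophil, lymphoid, and stromal and endothelial lists were higher in the UA-labelled libraries. Of 52 tested, 36 were called higher and 9 lower, and 25 had at least 5 CPM in WT. The lymphoid list and the mast cell and eosinophil list were not called by camera. Erythroid markers, left out of this set, went both ways. HBA2 had 44.7 CPM in UA against 68.1 in WT, and TFRC 569 against 92.4. Thinning all libraries to equal depth shifted the median log2 fold change of those 36 by -0.178, from 4.54 to 4.36. Thinning keeps the expected ratio between libraries, so this test had little room to come out otherwise. The deepest library was WT-labelled (25485143 counts) and the shallowest UA-labelled (6334264 counts), which argues against greater depth of the UA-labelled libraries as the source. A candidate explanation is a mixed marrow population behind the UA-labelled libraries, which picking of single colonies should exclude. Among genes too low to be tested, the lowest UA library had 2786 more with a count at equal depth than the highest WT library, but a gap of 3278 over all genes, already seen, left that test little room to come out otherwise. So a mixture and the TET2 genotype, which runs along the same labels and stays untested, cannot be told apart.

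The UA-labelled libraries differed little from each other. Depth is argued against, since at equal depth the smallest excess over counting noise of a WT pair was 1.91 times the largest of a UA pair. If the 3 libraries came from 1 RNA source, their excess should be under 2 times as large in the most abundant genes as in low ones for every pair. The largest ratio was 2.14, past that limit, but its bootstrap interval of 1.60 to 2.83 holds values on both sides of 2, so 1 source and 3 very similar colonies cannot be told apart. The TET2 genotype is again untested. Among all 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 9091 genes by edgeR, and the highest other called 0 (12 to 25 genes at an unadjusted p under 0.05 in the others). With 10 splits a share under 0.05 cannot be reached.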
